A study of Mus musculus with 8 samples.

How the data were processed

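RNA was measured in 8 samples of mouse keratinocytes, 2 from each of 4 lines: MK546 cells without α3 (null), and the same cells with human α3, with human α9, and with both. Per the labels' protocols, cells from α3-null newborn mice were immortalized with SV40 large T antigen and kept on collagen-coated plates (30 µg per ml) at 33 °C and 8% CO2, and 1 µg of total RNA was labelled after ribosomal RNA reduction. The platform was the Affymetrix Mouse Exon 1.0 ST array, which reads transcripts with many short probes along their exons. The deposited values are intensities on a linear scale, 1 per transcript cluster and array. Per the submitters' processing notes they were made with Affymetrix Expression Console and PLIER, a method that combines the probes of a cluster, and the series' own text also names the Exon Array Computational Tool. Versions, the genome build and any filter are not given in the sources used here. The authors' intensities do not share 1 distribution across arrays. Array medians were 95.0 and 94.3 in the null line, 109 and 97.4 with α3, 118 and 96.8 with α9, and 82.8 and 127 with both. Between 7.09% and 14.1% of values on an array lay under 16. Exon arrays give no read depth, so the number of arrays sets the precision. The 2 arrays of a line held identical values in 0 clusters, and replicate arrays correlated across clusters at 0.985 to 0.991. Arrays of different lines were not compared for identical values.

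Samples were grouped by their titles. Gene names came from the platform annotation, which is later than the arrays, with symbols matched by Entrez number to the mouse RefSeq gene table of assembly GRCm38.p6. That table served only for names and for which genes neighbour each other, since the build behind the files is not given, and no coordinates are printed. Of 23332 clusters, 14996 had 1 gene, 1019 several and 7317 were unlisted and stay unnamed here. For 14805 of 14860 genes the symbol matched that table. The 135 genes with several clusters were represented by the cluster with the highest mean over the 8 arrays.

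Values were taken as log2(intensity + 16) without further normalization and tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3, in 1 fit over all 8 arrays with a mean per line and 4 residual degrees of freedom. All 23332 clusters were tested, and p-values were adjusted by Benjamini-Hochberg within each of 5 contrasts, with a threshold of 0.05. The contrasts were α3 minus null, α3α9 minus α9, α9 minus null, α3α9 minus α3, and the difference of the first 2 (interaction). The titles mark null and α3 arrays as re-analysis and not the others, so the α9 contrasts are confounded with the set of arrays. Gene lists, 26 with 623 symbols of which 523 were measured, were tested with camera at a preset correlation of 0.01, adjusted over lists within a contrast, with camera at an estimated correlation and fry beside it. No list passed fry after adjustment in any contrast. The design, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule named Itga3, Itga9 and Itgb1, the 10 largest rises and 10 largest falls that passed with arrays not overlapping between lines (predicted genes passed over), up to 4 members of each list that passed, and all genes tied to α3β1 by earlier work. Genes outside it are named where a list count or a neighbouring block is described and were chosen after their values were seen.

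The fit was tested on simulated data with the real clusters' means, variances drawn from the distribution that limma fitted, and 200 changed clusters. There each cluster had the same spread in every line, and arrays did not differ in scale. On the real arrays the residual SD was 0.21 in the null line and 0.42 in the α3α9 line, so recovery may differ from the simulated values. Among 4-fold changes it recovered 86%, 91%, 94% and 88% in the 4 contrasts between lines and 17% in the interaction. Among 2-fold changes it recovered 12%, 10%, 10% and 15%, and 0% in the interaction. Alternatives were quantile normalization, centring on array medians, leaving out the lowest 25% of clusters by mean, an intensity trend or robust estimates in eBayes, the replicate number as a block, clusters with 1 gene, pseudocounts of 1 and 64, the 2 compared lines alone, and leaving out each array. Scaling each array to a common median before log2, and list counts without each array, were added after seeing the data. Where an array was left out, its line had 1 array, assumed to vary like the other lines. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. For the gene order, 7040 expressed genes were taken in 176 blocks of 40 and block medians were compared with 1000 shuffles of the order.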

Results

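The series measured RNA of MK546, an immortalized line of epidermal keratinocytes made from newborn mice that lack the integrin α3 subunit, and of 3 lines made from it. Integrins are receptors for extracellular matrix that pair an α with a β subunit. One derived line carried human α3 by stable transfection (α3 line), one carried human α9 by retroviral transduction (α9 line), and one carried both (α3α9 line). The parent without either subunit is called the null line. The 4 lines allow 2 questions: which keratinocyte genes differ with α3, and whether that difference changes where α9 is present. All lines grew at 33 °C in a medium with 0.05 mM calcium, 10 ng per ml EGF and 10 units per ml interferon-γ. Each of the 4 lines had 2 arrays, 8 in all, and their number limits the precision. The labels call them biological replicates and do not say that they came from separate cultures, so p-values measure the spread between these arrays, which may be technical. Values are the deposited intensities of 23332 transcript clusters, given as mean ± SD of 2 arrays (n = 2). Changes are log2 fold changes of intensity + 16 with their SE, which understate the change of dim transcripts, with adjusted p from limma. The median intensity of an array ranged from 82.8 to 127. The widest gap within a line was that of the α3α9 line, whose arrays had medians of 82.8 and 127. Titles mark the null and α3 arrays as re-analysis and leave the α9 and α3α9 arrays unmarked. Both α3 comparisons therefore lie within one set of arrays, and both α9 comparisons cross the 2 sets.

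The probes are for mouse transcripts, and the introduced subunits are human. Itga3 (transcript cluster 6791017) gave 971 ± 52.5 in the null line and 1245 ± 91.3 in the α3 line, a log2 difference of 0.35 ± 0.28 (adjusted p = 0.77). In the α9 and α3α9 lines it gave 954 ± 256 and 1089 ± 381. Itga9 gave 50.04 ± 3.77 in the null line, 63.2 ± 1.997 in the α9 line and 66.05 ± 17.5 in the α3α9 line. These signals neither check nor contradict the labels, since a null line can keep probed parts of the mouse transcript and a human transcript need not bind mouse probes. Itgb1, the β subunit that pairs with α3 and α9, gave 7501 ± 21.3, 5656 ± 409, 7739.6 ± 157 and 5392 ± 891 in the null, α3, α9 and α3α9 lines, and no comparison of it passed the test on the deposited scale. After quantile normalization Itgb1 was lower with α3 in both α3 comparisons, by log2 changes of -0.43 and -0.46 (adjusted p = 0.039 and 0.027), and so were Nrp1 and Pard3, which lie next to it in gene order.

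The first comparison asked which genes differ with α3 when α9 is absent. Sparc, a matricellular protein, rose from 361 ± 14.03 in the null line to 3751 ± 535 in the α3 line, a log2 change of 3.32 ± 0.21 (adjusted p = 6.8e-05). Fbln2, a matrix protein of basement membranes, rose from 523 ± 3.89 to 2197 ± 83.6 (2.04 ± 0.23, adjusted p = 0.0016). Krt19, a keratin of simple epithelia, rose from 915 ± 186 to 6179.6 ± 154 (2.75 ± 0.23, adjusted p = 2.5e-04). Ptgs2, the inducible cyclooxygenase, fell by 1.32 ± 0.24 on the log2 scale, from 3694 ± 221 to 1482 ± 247 (adjusted p = 0.028). Dsc3, a desmosomal cadherin, fell from 4222 ± 333 to 576 ± 13.2 (-2.84 ± 0.24, adjusted p = 2.4e-04).

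The 10 largest rises among named genes ran from 4.59 for Mctp1 to 3.45 for S100a8, a calcium-binding protein of inflamed epithelium. Between them lay Tnfrsf26, Lcn2, Speer3, Glipr2, Plscr2, Gatm, Tnip3 and Arhgdib. Tnfrsf26, Speer3 and Plscr2 have close relatives that may share probes, so their values are uncertain. The 10 largest falls ran from -6.51 for Slc25a13, a mitochondrial aspartate-glutamate carrier, to -2.84 for Dsc3. Akip1 and Pi15 lay under 16 in the α3 line, and Igf2bp3 gave 17.6 and 12.9 on its arrays, where the added 16 shrinks the change. Akip1 went from 1022 ± 156 to 1.08 ± 0.377, Pi15 from 1237 ± 102 to 12.03 ± 0.686, and Sostdc1, a secreted BMP and Wnt antagonist, from 12767 ± 988 to 130.0 ± 15.5. Pacs1, Slc50a1, Igf2bp3, Rcbtb2 and Tspan15 completed the falls.

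Of 33 measured inflammatory mediators, 7 rose and 1 fell, and 14 and 2 did when adjusted over the list alone. Lcn2, an iron-sequestering antimicrobial protein, rose from 78.03 ± 11.7 to 1808 ± 376, and Nos2, the inducible nitric oxide synthase, from 317 ± 31.3 to 1540.0 ± 21.6. The member that fell was Ptgs2. The list's camera test gave adjusted p = 6.7e-10 upward. Of 36 interferon response genes none rose and 3 fell (12 adjusted over the list alone), namely Gbp5 (-1.87), Ifit2 (-1.72) and Ifit1 (-1.60), with camera adjusted p = 1.1e-08 downward. These belong to families with similar sequences. Of 37 keratinocyte differentiation genes 2 fell (4 adjusted over the list alone), the cornified envelope precursor Sprr1a (-2.45) and Sbsn (-1.51), with camera adjusted p = 1.7e-04. Of 39 extracellular proteases and inhibitors 2 rose (4 adjusted over the list alone), the stromelysin Mmp3 (2.57) and the collagenase Mmp13 (1.65), with camera adjusted p = 6.6e-04. Of 25 secreted angiogenic factors 2 rose, Vegfc (2.53) and Edn1 (1.38), with camera adjusted p = 0.0035. Of 25 basement membrane genes 2 rose, Sparc and the nephronectin gene Npnt (1.59), with camera adjusted p = 0.039 upward, against a list median of -0.03 and a mean of 0.29. After quantile normalization that p was 0.32. Of 16 secreted angiogenesis inhibitors 1 fell, Thbs2 (-2.69), with camera adjusted p = 0.52. Of 37 cell cycle genes none passed, with a list median of -0.29 and camera adjusted p = 0.0012 downward, and 4 fell after quantile normalization. Without either α3α9 array 1 fell. Camera also passed downward for the epithelial junction list (adjusted p = 0.0044). With an estimated correlation between genes no list passed, adjusted p = 0.972 for each of them. Of 4 simple epithelium markers Krt19 rose, with camera adjusted p = 0.0012 upward and 0.015 after quantile normalization. None of the fibroblast, melanocyte, leukocyte or endothelial markers passed in this comparison. The list counts depended on single arrays. Without null replicates 1 and 2, 4 and 3 inflammatory mediators rose, and 3 did without either α3 array. No interferon response gene fell without null replicate 2 or either α3 array, and 6 fell without either α3α9 array. The differentiation list had 1 fall without null replicate 1 and none without null replicate 2 or either α3 array. The angiogenic list had 1 rise without any 1 of the null and α3 arrays, and the protease and basement membrane lists had 1 without either null array or α3 replicate 1.

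A list of 9 genes that earlier work tied to α3β1 in such lines had 5 measured members, since the Prl2c genes had no row of their own. Sparc and Fbln2 rose and Ptgs2 fell, with camera adjusted p = 0.0012 upward, 0.058 after quantile normalization and 0.972 with an estimated correlation. Mmp9, a gelatinase, gave 63.2 ± 7.11 in the null line and 100.1 ± 33.02 in the α3 line (0.52 ± 0.26, adjusted p = 0.52), and Bmp1 gave 0.07 ± 0.20 (adjusted p = 0.97). The same arrays may have served that work, so the list is not independent evidence of its direction. In all, 303 clusters passed, 221 higher and 82 lower with α3, over a median of all clusters of 0.01. The share of higher calls depended on the scale of the arrays: after quantile normalization 1046 were higher and 877 lower, and after centring 684 and 749. The 303 calls kept their direction in both, 303 and 302 of them past the threshold. Without single null or α3 arrays the count was 136, 130, 102 and 134, and without either α3α9 array, which enters through the shared spread, 536. Of the named calls 27 of 43 held without each array in turn. The 16 others, among them Ptgs2, Edn1, Mmp13, Sprr1a, Sbsn, Gbp5, Ifit1 and Ifit2, were lost without at least 1 array. Their sign could not change there, since the arrays of the compared lines did not overlap for any call.

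**Figure D1:**
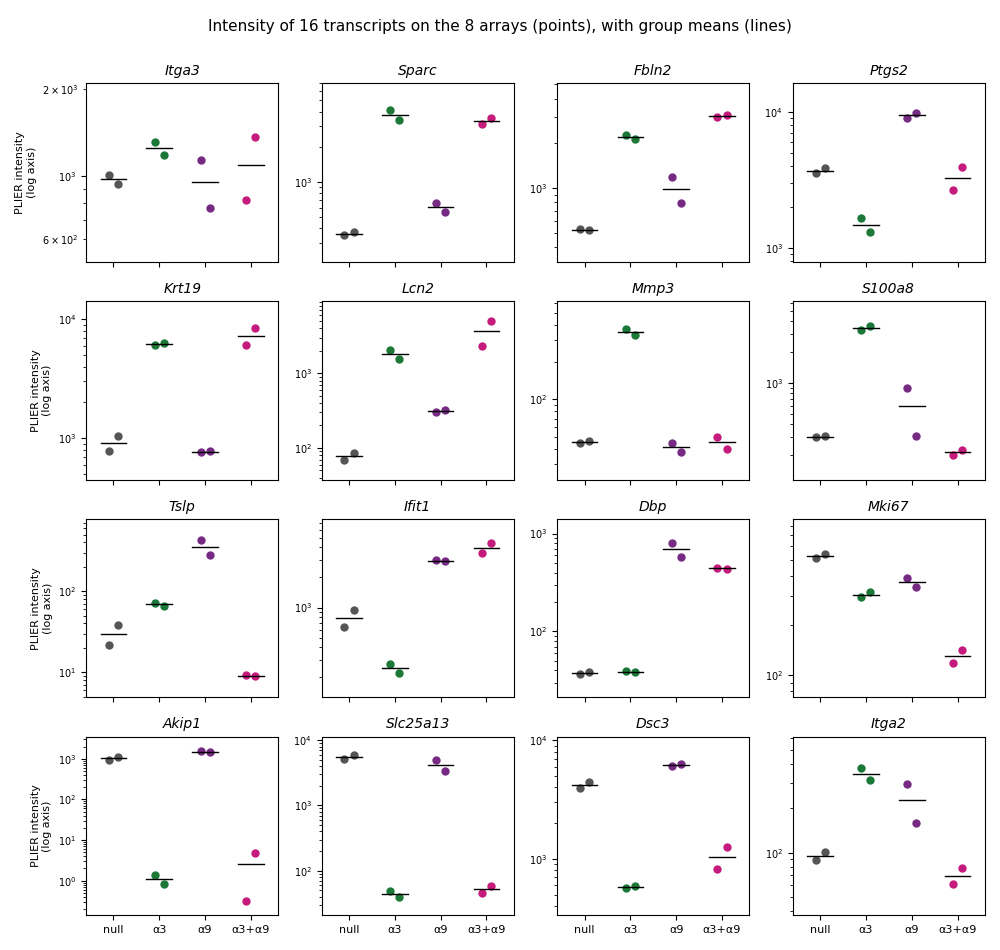
Deposited intensity (log axis) of 16 transcripts on the 8 arrays, grouped by line; each point is 1 array and each line the mean of 2. Sparc and Fbln2 lie higher, and Akip1, Slc25a13 and Dsc3 lower, in both lines with α3, while Dbp lies higher in both lines with α9.

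The second comparison asked for the effect of α3 when α9 is present, between the α3α9 and α9 lines. Sparc rose from 610.4 ± 73.8 to 3322 ± 283 (2.42 ± 0.21, adjusted p = 3.7e-04), Fbln2 from 985 ± 278 to 3046 ± 58.3 (1.64 ± 0.23, adjusted p = 0.0057) and Krt19 from 776 ± 18.9 to 7231 ± 1596 (3.18 ± 0.23, adjusted p = 1.2e-04). Ptgs2 fell from 9476 ± 503 to 3292 ± 906 (-1.55 ± 0.24, adjusted p = 0.01). The epithelial cytokine Tslp fell from 356 ± 103 to 9.06 ± 0.26 (-3.86 ± 0.26, adjusted p = 6.5e-05). Mki67, a marker of proliferating cells, fell from 364 ± 31.03 to 131 ± 16.7 (-1.38 ± 0.20, adjusted p = 0.0068).

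The largest rises were those of Gatm (4.47), a creatine synthesis enzyme, Car6 (4.47), a secreted carbonic anhydrase, and Susd4 (4.36), followed by Lcn2, Krt19, Mcam, Klf15, Mgmt, Kcnj15 and Gask1b. The largest falls were again those of Akip1 (-6.35), Pi15 (-6.25), Slc25a13 (-5.92), Slc50a1 (-5.65) and Pacs1 (-5.30), followed by Rbms3, Mapk12, Tslp, Tmem159 and Pgpep1. Of 37 cell cycle genes 8 fell and none rose (20 fell when adjusted over the list alone), among them the mitotic kinase Plk1 (-1.14), Top2a (-1.17) and the replication helicase subunit Mcm5 (-1.07). The camera test gave adjusted p = 1.1e-15 downward. After quantile normalization 23 cell cycle genes fell and none rose, with camera adjusted p = 2.6e-16, and 0.379 with an estimated correlation. Of 37 keratinocyte differentiation genes 7 fell and 1 rose (13 and 1 adjusted over the list alone), with camera adjusted p = 1.6e-10. The fallen members included Sprr1a (-2.73), Sprr2h (-2.03), Sprr1b (-1.80) and Sprr2d (-1.66), a family whose members may share probes. Krt16, a keratin of activated epidermis, fell from 2603 ± 24.4 to 327 ± 148. Of 26 genes of ERK pathway output 3 rose, Fosl1 (1.94), Fos (1.74) and the ERK phosphatase Dusp6 (1.69), with camera adjusted p = 0.0048. Camera also passed downward for the epithelial junction (adjusted p = 0.0048), TGF-β target (0.018) and basal keratinocyte (0.035) lists. With an estimated correlation no list passed, adjusted p = 0.985 for each. Of 25 basement membrane genes 3 rose, Sparc, Col4a1 (1.60) and Npnt (1.33), and the camera adjusted p was 0.018 upward and 0.15 after quantile normalization, against a list median of -0.05. The 40 genes of the gene-order block from Insr to Cln8, which holds Col4a1, had a median change of 0.62 here and 0.64 without α9 after quantile normalization. Flt1 (1.23) was the 1 endothelial marker that rose, and no fibroblast, melanocyte or leukocyte marker passed. Of 4 simple epithelium markers Krt19 rose, with camera adjusted p = 0.0092 upward and 0.053 after quantile normalization.

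In all, 436 clusters passed, 244 higher and 192 lower with α3, against 1257 and 597 after the arrays were scaled to a common median, over a median of all clusters of -0.06. The split turned on the α3α9 arrays. Without replicate 1 of that line, 409 clusters were higher and 113 lower. Without replicate 2, 158 were higher and 760 lower. The cell cycle list had 2 falls without replicate 1 and 13 without replicate 2, and the differentiation list had 4 and 12. Without α9 replicates 1 and 2 the cell cycle list had 0 and 1 falls, and 2 without any 1 of the null and α3 arrays. Without α9 replicate 2 the differentiation list had 3 falls, the ERK and basement membrane lists 1 rise each, and the endothelial markers none. Without α9 replicate 2 the count was 169, and without either α3 array 290. Of 51 named calls 31 held without each array in turn. The 20 others, among them Fbln2, Ptgs2, Col4a1, Mki67, Plk1, Top2a, Mcm5, Fosl1 and Dusp6, were lost without at least 1.

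The 2 α3 comparisons share no array and could be set side by side. Of the 303 clusters that passed without α9, 275 (90.8%) had the same sign with α9, and 169 also passed there in the same direction, 114 higher and 55 lower. Independent lists would share 2.31 and 0.675, but both comparisons used the same estimate of spread for each cluster, so independence is not a strict baseline. The labels do not give the origin of the α3α9 line, so the overlap need not come from α3. The 3 clusters that passed in opposite directions were too few for a group. Across these 303 clusters the slope of the effect with α9 on that without was 0.76 (95% interval 0.71 to 0.82) and Pearson's r across genes was 0.85. Genes are not independent replicates, so the interval describes these clusters alone. Starting from the 436 clusters that passed with α9, 389 had the same sign without α9, with a slope of 0.66.

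**Figure D2:**
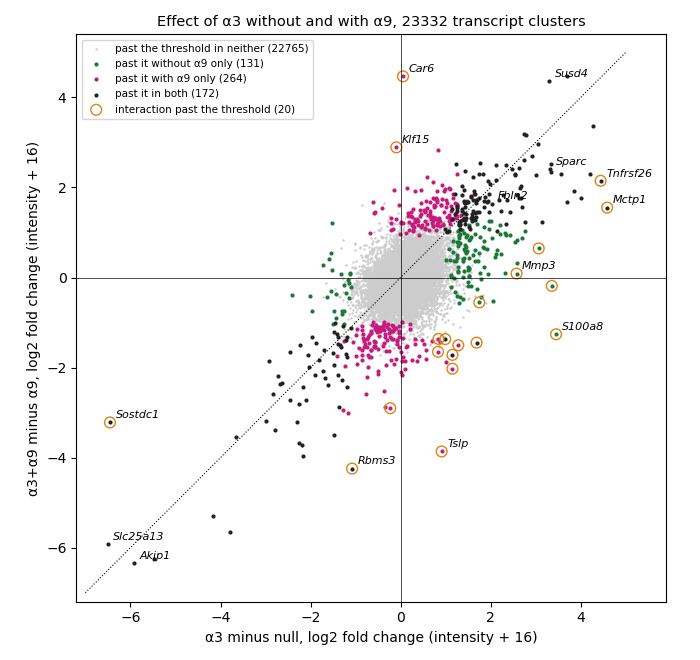
Log2 fold change with α3 without α9 (horizontal) and with α9 (vertical) for 23332 transcript clusters; colour marks in which comparison a cluster passed and open circles mark the 20 with an interaction. Akip1 and Slc25a13 lie low on both axes, and Tslp, S100a8 and Mmp3 lie off the dotted line of equal change.

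The interaction asked whether the α3 effect differs with α9 present, a contrast in which an additive shift between the array sets cancels. Each combination of subunits was 1 line, so other differences between the lines do not cancel. Mmp3 rose with α3 in the absence of α9, from 45.4 ± 1.63 to 350.0 ± 29.2, and gave 41.2 ± 4.89 and 44.9 ± 7.06 in the lines with α9, an interaction of -2.49 ± 0.28 (adjusted p = 0.015). S100a8 rose from 300.3 ± 6.16 to 3449 ± 209 without α9 and gave 601 ± 417 and 210.3 ± 17.1 with it (-4.71 ± 0.55, adjusted p = 0.017). Itga2, the α subunit of a collagen receptor, rose by 1.69 without α9 and fell by 1.45 ± 0.28 with it (-3.13 ± 0.40, adjusted p = 0.026). Tslp had an interaction of -4.77 ± 0.36 (adjusted p = 0.0034). In the other direction, Car6 gave 84.5 ± 11.02 and 87.98 ± 5.60 without α9 and rose from 108 ± 3.11 to 2830.3 ± 1041 with it (4.41 ± 0.37, adjusted p = 0.0039). The transcription factor Klf15 had an interaction of 2.99 ± 0.36 and Sostdc1 one of 3.24 ± 0.34.

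Sparc, Fbln2 and Ptgs2 had interactions of -0.90 ± 0.29, -0.39 ± 0.32 and -0.23 ± 0.34 (adjusted p = 0.63, 1 and 1), so a difference between their α3 effects was not detectable with these arrays. Among the lists, 2 of 33 inflammatory mediators were lower in the interaction, S100a8 and Tslp (camera adjusted p = 2.3e-07 downward), and 1 was without either α3 array or α3α9 replicate 1. No cell cycle or interferon response gene passed (camera adjusted p = 9.8e-08 downward and 6.7e-08 upward). Camera also passed upward for ERK output (adjusted p = 1.7e-04) and downward for TGF-β targets, YAP and TEAD targets and differentiation (each 0.0070), proteases (0.018) and the earlier-work list (0.044), of which differentiation and proteases did not pass after quantile normalization (0.069 and 0.074). With an estimated correlation no list passed, adjusted p = 0.996 for each. In all 20 clusters passed, 3 higher and 17 lower. Of 23332 clusters 1329 had an unadjusted p under 0.05 in limma's test, little above the share of 0.05 expected without any change. That holds for the deposited scale. By the same test 3672 had one after quantile normalization and 3445 after centring, well above that share. After quantile normalization the split was 72 and 100, and after centring 66 and 76, with all 20 calls among them. With a pseudocount of 1 no cluster passed limma's test, and 1139 had an unadjusted p under 0.05, no more than that share. In simulated data with 200 changed clusters and the same spread in every line, this contrast recovered 17% of 4-fold changes and 0% of 2-fold changes. A missing call therefore says little. Without α3α9 replicate 2 there were 202 calls, 196 of them lower, and without α3 replicate 1 there were 2. Without replicate 1 or 2 of the null line there were 7 and 8, without α3 replicate 2 there were 5, without the α9 replicates 12 and 11, and without α3α9 replicate 1 12. Of the 13 named genes Car6 and Tslp held without each array in turn, and the highest adjusted p of the others was 0.201.

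The third comparison set the α9 line against the null line. Here α9 and the set of arrays cannot be told apart, because each set holds lines of 1 α9 state. Rsad2, an antiviral enzyme induced by interferon, rose from 593 ± 31.2 to 3994 ± 569 (2.71 ± 0.21, adjusted p = 3.6e-04). Dbp, a transcription factor under circadian control, rose from 37.9 ± 1.31 to 694 ± 160.0 (3.70 ± 0.21, adjusted p = 7.7e-05). The glycolytic regulator Pfkfb3 rose from 203 ± 8.32 to 1968 ± 296 (3.17 ± 0.20, adjusted p = 1.1e-04). Sostdc1 fell from 12767 ± 988 to 718 ± 144 (-4.13 ± 0.24, adjusted p = 7.7e-05), and Dusp6 from 2958 ± 340.2 to 416 ± 247 (-2.91 ± 0.35, adjusted p = 0.0035). Ptgs2 rose from 3694 ± 221 to 9476 ± 503 (1.36 ± 0.24, adjusted p = 0.016), and Sparc gave 0.73 ± 0.21 (adjusted p = 0.083).

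The 10 largest rises also held Rbms3 (3.50), Oas2 (3.26), Crebrf, Tslp (3.02), Oasl1, Edn2, Pim1 and Ncam1. The largest falls held Gpx2 (-3.98), a glutathione peroxidase of epithelia, Mrto4, Ube2n, Esd, H4c14, Tnfaip8, Bbs12 and Kbtbd8. Of 36 interferon response genes 10 rose and none fell (15 and 2 adjusted over the list alone), with camera adjusted p = 2.1e-05. They included Irf7 (2.27), Ifit1 (1.90) and the chemokine Cxcl10 (1.95). After quantile normalization 13 rose and 6 fell, with camera adjusted p = 0.022 upward. No cell cycle gene passed, with camera adjusted p = 6.1e-06 downward, and 1 rose and 20 fell after quantile normalization. Of 20 YAP and TEAD targets 8 rose, among them Rbms3, tissue factor F3 (2.14), Amotl2 (1.60) and Nt5e (1.59), with camera adjusted p = 2.9e-07. Of 37 differentiation genes 8 rose, led by corneodesmosin Cdsn (2.71) and Krt78 (1.88), with camera adjusted p = 0.032 and 0.15 after quantile normalization. Of 33 epithelial junction genes 3 rose, Cdh13 (1.36), Pkp1 (1.17) and Grhl1 (1.08), with camera adjusted p = 0.0040. Of 26 ERK output genes 3 fell, Dusp6, Fosl1 (-1.91) and Ier2 (-1.42), with camera adjusted p = 6.1e-06. With an estimated correlation no list passed, adjusted p = 0.956 for each. Cd68 (1.11) was the 1 leukocyte marker that rose.

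In all, 1009 clusters passed, 817 higher and 192 lower in the α9 line, over a median of all clusters of 0.16. After quantile normalization 2066 were higher and 1942 lower, and after centring 1852 and 1479, over medians of 0.00 and 0.01. Without null replicate 1 or 2 the count was 156 and 174, without α9 replicate 1 or 2 304 and 288, without either α3 array 558, and without either α3α9 array 2532. Without either null array 3 YAP and TEAD targets rose, without α9 replicate 1 4, without either α3 array 5, and without either α3α9 array 10. The differentiation list had 2 rises without either null or either α9 array. The junction list had none without either null array or α9 replicate 1, 1 without α9 replicate 2 and 7 without either α3α9 array. The ERK list had 1 fall without null replicate 2, and the cell cycle list 4 falls and 1 rise without either α3α9 array. Of 64 named calls 26 held without each array in turn. The 38 others, among them Ptgs2, Amotl2, Nt5e, Cdh13, Pkp1, Grhl1, Fosl1, Ier2, Esd and Cd68, were lost without at least 1.

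The fourth comparison set the α3α9 line against the α3 line, under the same limit that α9 and the set of arrays cannot be told apart. Ifit1 rose from 246 ± 38.8 to 3959 ± 669 (3.92 ± 0.24, adjusted p = 1.1e-04) and Irf7, a transcription factor of the interferon response, from 418 ± 113 to 3891 ± 428 (3.19 ± 0.25, adjusted p = 2.6e-04). Cdsn rose from 214 ± 28.5 to 3471 ± 945 (3.90 ± 0.24, adjusted p = 1.1e-04). S100a8 fell from 3449 ± 209 to 210.3 ± 17.1 (-3.94 ± 0.39, adjusted p = 9.8e-04), and Mmp3 from 350.0 ± 29.2 to 44.9 ± 7.06 (-2.59 ± 0.20, adjusted p = 2.6e-04). Vegfd, an angiogenic growth factor, rose from 454 ± 77.4 to 1624 ± 428 (1.79 ± 0.24, adjusted p = 0.0057).

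The largest rises also held Trim30a (4.82), Car6, Ifit2, Oas2, Rsad2, Klf15 and Dbp (3.06), and the largest falls Gpx2 (-3.69), Mctp1, Tnip3, Glipr2, Il5ra, Csf2, Mrto4, Txnip and Gimap9. Of 36 interferon response genes 15 rose and none fell (19 and none adjusted over the list alone), with camera adjusted p = 3.2e-15. In that list 17 and 14 rose without α3α9 replicates 1 and 2, and 8 rose without either α3 array. Of 33 inflammatory mediators 9 fell and 2 rose (13 and 3 adjusted over the list alone), with camera adjusted p = 6.7e-09. Without α3α9 replicate 1, 7 fell and 3 rose, with a list median of 0.06 against -0.20, and without replicate 2, 12 fell and 1 rose. Without α3 replicates 1 and 2, 1 and 2 fell. The fallen ones included S100a8, Csf2 (-2.79) and Il23a (-1.94), and those that rose were Ccl5 (1.89) and Ptgs2 (1.13). Of 37 cell cycle genes 11 fell and none rose (23 and 1 adjusted over the list alone), among them the centromeric histone Cenpa (-1.81), Birc5 (-1.32) and Mki67 (-1.14), with camera adjusted p = 1.1e-19. Without α3α9 replicates 1 and 2, 7 and 17 fell, without either null array 5, and without α3 replicates 1 and 2, 0 and 1. After quantile normalization 29 cell cycle genes fell and 1 rose, with camera adjusted p = 2.96e-17, and 0.345 with an estimated correlation. Of 20 YAP and TEAD targets 2 rose, F3 (2.48) and Amotl2 (0.94), with camera adjusted p = 0.0034. Without α3α9 replicate 1, 6 rose, and 1 did without any other single array. Camera also passed upward for the epithelial junction list (adjusted p = 0.018). With an estimated correlation no list passed, adjusted p = 0.995 for each. None of the fibroblast, melanocyte, leukocyte or endothelial markers passed.

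In all, 765 clusters passed, 499 higher and 266 lower, over a median of all clusters of 0.10, against 2352 and 2046 after quantile normalization. Which direction held the majority depended on the α3α9 arrays: without replicate 1, 2016 were higher and 197 lower, and without replicate 2, 345 and 1217, with 679 and 590 of the 765 calls among them. Without α3 replicate 1 or 2 the count was 88 and 119, and without either null array 453. Of 54 named calls 26 held without each array in turn. The 28 others, among them Ptgs2, Vegfd, Amotl2, Cenpa, Birc5, Mki67, Csf2, Il23a and Ccl5, were lost without at least 1. The 2 α9 comparisons shared 336 calls, 271 higher and 65 lower, where independent lists would share 17.5 and 2.19. The shared estimate of spread and the array sets limit this baseline too.

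**Figure D3:**
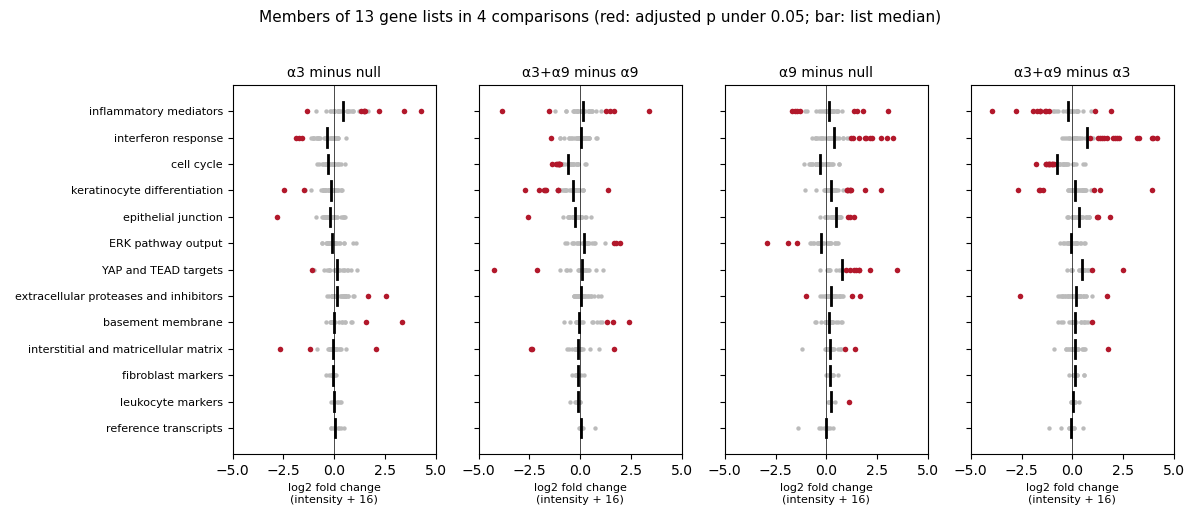
Log2 fold change of the measured members of 13 gene lists in 4 comparisons; each point is 1 gene, red points passed the test and bars are list medians. Of 36 interferon response genes 10 and 15 rose in the α9 comparisons, and of 37 cell cycle genes 8 fell with α3 in the presence of α9.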

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

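The tests of explanations in this part were chosen after the results they address were seen. For 17 genes the effect of α3 differed with α9 present by the interaction test fixed beforehand, given as the log2 effect with α9 minus that without. Tslp (-4.77), S100a8 (-4.71), Itga2 (-3.13), Sulf1 (-2.87), Il5ra (-2.78), Prl8a9 (-2.48), Prl8a6 (-2.36), Adam22 (-2.30) and Serpinb6c (-2.20) had positive estimates without α9 and negative ones with it. Mctp1 (-3.03), Tnfrsf26 (-2.29), Mmp3 (-2.49) and Mcpt8 (-2.42) had larger positive estimates without α9. Rbms3 (-3.17) fell in both comparisons, from 1194 ± 92.9 to 48.1 ± 9.83 with α9. Car6 (4.41) and Klf15 (2.99) rose with α3 where α9 was present, and Sostdc1 (3.24) fell in both comparisons, less so with α9.

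In the α9 comparisons 10 and 15 of 36 interferon response genes rose without and with α3, and 11 cell cycle genes fell with α3, while no list passed camera with an estimated correlation (adjusted p = 0.956 and 0.995). With α3 present, a different overall scale of the arrays is argued against as the whole source for the interferon list, whose median after quantile normalization was 0.62 (0.616). Without α3 its median went from 0.37 to 0.20 (0.197), while the median of all clusters went from 0.16 to 0.00. After quantile normalization 13 members were higher and 6 lower. Camera's adjusted p was then 0.022 upward, and 0.546 with an estimated correlation. The scale stays open there. That all 10 interferon genes that rose on the deposited scale passed again rests on genes already called and decides nothing. A difference between the array sets, or in how cells were handled for them, cannot be told apart from α9, because the number of sets that hold lines with and without α9 is 0. An effect of α9 itself, of the retroviral transduction or of its response to the interferon-γ in the medium may each be the source, and none of these was tested.

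Akip1, Pi15, Slc25a13, Slc50a1 and Pacs1 had intensities of 0.323 to 74.96 on the arrays with α3 and 911 to 5874 on those without. The scale of the arrays is argued against, since the smallest of their falls after quantile normalization was by 3.89 on the log2 scale. A loss of segments spanning 5 genes on each side is argued against too, since the 50 neighbours had medians of -0.01 (-0.00618) and 0.00 in the α3 comparisons, but a shorter loss is not excluded, as Crispld1 near Pi15 had -0.91 and Cst6 near Pacs1 -0.66 without α9. An origin of both lines from 1 transfected clone that had lost these transcripts may account for them, and so may α3 itself. These cannot be told apart, because there is 1 group with α3 and without α9 and the labels do not give the origin of the α3α9 line.

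Across the clusters that passed without α9, the α3 response looked smaller with α9 present, with a slope of 0.76. Selecting the largest changes of 1 comparison may be enough to give such a slope, since the selection from the other side gave 0.658, also under 1. Of 20 interactions 17 were lower, which means a more negative α3 effect with α9 and not always a smaller one. Tslp changed by 0.91 without α9 and by -3.86 with it, and Mmp3 by 2.57 and 0.09. All 17 lower interactions passed in the same direction after centring, which rests on clusters already called and decides nothing about the scale of the arrays. Centring moved the median of all interactions from -0.06 to 0.09. That shift is small beside the lower interactions of the 14 clusters with 1 gene, from -4.77 to -2.20. Lower interactions also outnumbered higher ones after centring (76 and 66) and after quantile normalization (100 and 72), as a smaller majority, and the source of the excess was not tested. An effect of α9 on the response of single genes, such as Car6 and Tslp, stays open, and so does another difference between the lines.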

How the results depend on the processing

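None of the 225 named calls reversed its sign under the alternatives run. Without single arrays this was fixed in advance for calls between lines, since their arrays did not overlap, so it says nothing about robustness there. The majority direction of the calls did reverse: for α3 without α9 under centring (684 higher, 749 lower) and scaling (652, 707), for α3 with α9 without α9 replicate 2 (63, 106) and without α3α9 replicate 2 (158, 760), and for α9 with α3 without α3α9 replicate 2 (345, 1217) and with the 2 compared lines alone (415, 442). Scaling to a common median, and centring and the replicate block for the slope, were chosen after seeing the data. Counts are given in the order α3 without α9, α3 with α9, α9 without α3, α9 with α3 and interaction, against 303, 436, 1009, 765 and 20. Quantile normalization gave 1923, 2328, 4008, 4398 and 172, centring 1433, 1916, 3331, 4363 and 142, and scaling 1359, 1854, 3107, 4199 and 139. Clusters with 1 gene gave 815, 1115, 2170, 2081 and 149, and a pseudocount of 1 gave 151, 174, 211, 165 and 0. There limma left 1139 interactions with an unadjusted p under 0.05, no more than the share of 0.05 expected without any change. Leaving out the lowest 25% of clusters gave 1384 for α9 with α3 and 59 interactions, a pseudocount of 64 gave 1380 for α9 with α3, and the 2 compared lines alone gave 568 for α3 without α9. The slope of 0.76 became 0.640, 0.652 and 0.653 under quantile normalization, centring and scaling. The 38 list calls became 0 with an estimated correlation, which lowers camera's power by construction. The estimates ran from 0.25 to 0.78 over the lists, far above the preset 0.01. The small p-values of camera at the preset therefore rest on an assumption that these estimates do not bear out. The other causes were not tested. Leaving out single arrays gave 102 to 536, 169 to 918, 156 to 2532, 88 to 2213 and 2 to 202 calls and slopes of 0.72 to 0.80. Of 225 named calls, 7 to 70 were lost without 1 array, 100 with a pseudocount of 1 and 16 with the block. An intensity trend and robust estimates kept every count within 1.5 times.

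Replicate numbers did not pair the samples, with correlations of deviations between -0.21 and 0.07. The replicate block gave 482 calls for α9 with α3 and kept the other counts within 1.5 times. Between 7.09% and 14.1% of values on an array lay under 16, where the pseudocount makes up most of the value that is tested.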

Other observations

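In this part, the tests of the gene order were chosen after the result was seen, and those of clock and prolactin genes before. Some further genes passed in more than 1 comparison. Mcam, a cell adhesion molecule, gave 245 ± 16.5 and 1805 ± 271 without α9 and 219.6 ± 19.3 and 2112 ± 379.8 with it. Lgals7, a galectin of stratified epithelium, was highest in the α3α9 line, at 6781 ± 703 against 351 ± 50.1 in the null line. Gpx2 gave 1748 ± 84.5, 269 ± 22.1, 96.7 ± 18.04 and 7.17 ± 10.03 in the null, α3, α9 and α3α9 lines. Among integrin subunits, Itgb5 rose in both α9 comparisons (1.24 and 1.07) and Itgb7 did too (0.88 and 1.76), under the limit of the array sets. Without α3 the call of Itgb5 was lost without either null array or α9 replicate 1 (adjusted p up to 0.152) and that of Itgb7 without any 1 of the null, α3 and α9 arrays (up to 0.348). With α3 that of Itgb5 was lost without any 1 of the null and α3 arrays (up to 0.206), and that of Itgb7 held without each.

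Neighbouring genes moved together in both lines with α3. Among 156 placed genes that passed in the same direction in both α3 comparisons there were 14 neighbouring pairs within 5 genes, against a median of 5 in 10000 random sets matched on expression (share with as many 8e-04). The medians of 176 blocks of 40 genes had an SD of 0.152 without α9, above the highest of 1000 shuffled orders (0.0782), after quantile normalization, so the scale of the arrays is argued against. The α9 comparisons also exceeded every shuffled order, by less, with SDs of 0.112 (highest shuffled 0.102) and 0.116 (0.0996), and so did the interaction, with 0.0983 (0.0702). Of the 10 and 7 blocks at least 0.3 from the median in the α3 comparisons without and with α9, 4 were shared. The block from Insr to Cln8 had medians of 0.64 and 0.62 with α3 and 0.00 in both α9 comparisons. Some blocks differed between the α3 comparisons. That from Actr1a to Vax1 had -0.29 without α9 and -0.04 with it, with an interaction median of 0.35. That from Insl6 to Rrp12, which holds Ifit1, had -0.28 and 0.08. The 8 blocks from Ppp1r14c to Pip4k2c (320 genes), all those of their chromosome, were lower in both α3 comparisons, with medians of -0.46 to -0.26 and -0.35 to -0.14, and the 8 from Gsr to Exoc8 had -0.36 to -0.20 and -0.27 to -0.01. Of 10000 shuffled block orders a share of 0.0201 held a run of 8 or more, and the longest was 11. A difference in copy number shared by the 2 lines with α3 may account for blocks shifted in both comparisons, but not for a difference between them. For co-regulation of small gene clusters 2 statistics were tried. The longest run, 8, decides nothing, as the first of these runs fills its chromosome and could not have been longer. The other was chosen after that: 58 of 136 pairs of blocks 2 apart lay on the same side in both comparisons. Shuffled orders had a median of 37, a 95th percentile of 45 and a highest of 56. The 2 runs, seen before, give 12 of these pairs. The other 46 lie above the 95th percentile and under the highest, but the shuffles kept the blocks of the runs, so that comparison is unequal. For the blocks at large co-regulation therefore stays open. For the 320 genes from Ppp1r14c to Pip4k2c the block medians argue against small clusters as the whole source. All 8 lay at -0.26 or lower without α9 and at -0.14 or lower with it. Block medians of shuffled gene orders had a median SD of 0.0667 and 0.0654 in these comparisons. This chromosome was picked for its run, so the values cover its genes alone. In the block from Insr to Cln8 65% of the 40 genes rose in both comparisons, under the limit of 75% set for copy number. That limit was set after the block median was seen, and the share was not computed for other blocks, so it decides nothing about copy number. The next block, from Mcph1 to Ubxn8, had medians of 0.33 and 0.52. Both lie just before the 8 lower blocks from Gsr to Exoc8, on a chromosome of 10 blocks. DNA was not measured here.

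Output genes of the circadian clock, from a list written before its test, had medians of 1.04 and 0.68 (0.675) in the α9 comparisons after quantile normalization, led by Dbp. A different clock phase of the cultures may be the source, but genes of the opposite phase had medians of 0.13 and 0.10 rather than a fall, and the array sets are confounded with α9, so the phase cannot be told apart from other sources. Genes of the prolactin family may rise with α3 where α9 is absent: their median was 0.302 after quantile normalization and that of the interaction -0.31, with 2 of 14 rising without α9 and 3 falling with it on the deposited scale. Of the 14, 6 had a mean under 16 in the null line, so few members carry these values. Both medians met the limits of 0.3 and -0.3 set beforehand. A margin of 1 SE of the median, added after the values were seen, was not met, and with it the question stays open.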
